A study of Mus musculus with 49 samples.

How the data were processed

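RNA-seq of white fat was compared between the mouse strains C57BL/6 and 129S1/SvImJ. The labels give 49 samples, of which the 43 libraries of 5 deposited tables were used. 5 libraries of chow-fed F1 mice and 1 nascent RNA (GRO-seq) sample were not analysed here, and neither were the planned comparisons with F1 mice. Drug-experiment mice ate low fat control diet from 6 to 16 weeks of age, then the same diet without or with 36 mg rosiglitazone per kg until 18 weeks. RNA was taken up with Trizol and RNeasy columns, and TruSeq libraries were sequenced on an Illumina Genome Analyzer. HOMER and the mouse genome build mm9 are named per the submitters' processing notes, and the counting options and the normalization step are not given in the sources used here.

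Each table gives, per transcript, a score for every library, which as deposited was a whole number with a floor of 1, already normalized by the authors. Within an experiment all libraries share their highest values and nearly the same total, as quantile normalization leaves them, so these are not raw counts and the depth per library is unknown. The library totals of 5537632 to 7526303 are sums of normalized values, and no counting interval was computed. The 8 control diet libraries stand in both tables of the drug experiment, with identical values, and these tables were normalized together. The eWAT and iWAT tables of the low fat diet experiments also share their highest values, so depots were compared across them. The chow table was normalized on its own, so no level is compared between it and the others. The deposited tables also hold the authors' log2 fold change per transcript, whose program is not given in the sources used here. They hold the authors' p-value per transcript, and whether it was adjusted is not given in the sources used here. 11 columns of per-sample values could not be mapped to a sample and were not used. Column names were matched to samples by the library numbers in the labels.

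Of the 28644 transcript rows, the one with the highest total over all libraries was kept for each of 22869 gene symbols. The planned filter, a value of at least 1 in as many libraries as the smallest group, removed no gene. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, by linear models with 1 mean per group and moderated statistics with trend and robust settings. The plan had branches for counts and for normalized values, and the values called for the second. There were 11 comparisons. The chow, 12-week eWAT and 12-week iWAT strain comparisons were fitted each on its own libraries, the drug experiment in 1 fit of its 16 libraries, and the depot comparisons in 1 fit of 17 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and all tests were two-sided. Correlation between libraries of 1 group lay between 0.848 and 0.994. Replicate numbers were checked for pairing, and in none of 13 pair sets did libraries of the same number resemble each other in the way set beforehand, so no pairing was used.

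22 gene lists were fixed with the comparisons, the tests, the named-gene rule and the other settings to try before the data were examined. They were adipocyte identity and lipid storage, textbook PPARG agonist responsive, thermogenic, fatty acid oxidation, respiratory chain and citrate cycle, fatty acid synthesis, sterol synthesis and uptake, insulin signalling and adipokines, macrophage, lymphocyte, extracellular matrix, mesothelial, endothelial, skeletal muscle, epididymis, skin and glandular epithelium, erythroid, positional, interferon response, circadian clock, immediate early response and cell cycle. Each was tested in each comparison (242 tests) with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 97 lists called, 12 were also called with an estimated correlation, and chance alone calls about 1 in 20 unadjusted tests. Median, mean and test differed in sign in 34 of the 242 list tests, and in 0 of those called. Members were counted with p adjusted over all genes and adjusted over the list alone. A library was set apart where a marker list of another tissue or cell type lay more than 2 log2 units above its group median.

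By the rule, genes were named per comparison as the 6 largest called fold changes in each direction without overlap between groups and with a mean of at least 5 in the higher group, up to 4 members of each list with the smallest p, and the fixed genes Pparg, Adipoq, Fabp4, Cd36, Ucp1, Nnt and agouti. For interactions no condition on overlap was set. The rule gave more genes than the text can hold. The 305 candidates, counted per comparison, were narrowed to 211 after the fits without single libraries had been seen, partly by how stable their calls were, and some of the candidates are not reported here for other reasons. Of the candidates 260 were called, 208 of them whichever library was left out, and of the genes in the text 171 were called, 162 whichever library was left out. The genes in the text are therefore steadier than the rule alone would give. Small nucleolar RNA genes were singled out after their values were seen. Genes with near-identical copies elsewhere in the genome, such as Rprl3 and Rpl29, have uncertain values.

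The steps were tested on simulated data made from these libraries, with 200 genes changed per comparison and a further gene list shifted by 1 log2 unit. Of genes changed by 1 log2 unit, 5% to 82% were called across comparisons, and of genes changed by 2 units 34% to 100%, with the fewest in the iWAT strain comparison. There 10 of 49 calls were false (20.4%), 9 of them genes with means under 20, and in the other comparisons 1.28% to 10.4%. Other settings chosen beforehand were a pseudocount of 0.1, quantile normalization of the log2 values, all transcript rows, a fold change threshold, a stricter adjusted p of 0.01 for shared genes, only the groups compared, replicate number as a block, leaving out each library, and camera with an estimated correlation or fry for lists. Added after the data were seen were filters at a value of at least 2 or a group mean of at least 20, array weights, fits without the libraries set apart, and shared genes and lists with single libraries left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.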

Results

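Expression was measured by RNA-seq in white fat of 2 inbred mouse strains, C57BL/6 and 129S1/SvImJ. Epididymal white adipose tissue (eWAT), a visceral depot, was sampled on chow (5 libraries per strain), on a low fat control diet with or without rosiglitazone (4 libraries per strain and diet), and, in other experiments, after 12 weeks of low fat diet (5 C57BL/6 and 4 129S1/SvImJ libraries). Inguinal white adipose tissue (iWAT), a subcutaneous depot, was sampled after the same 12 weeks (4 libraries per strain). Rosiglitazone, an antidiabetic drug that activates the nuclear receptor PPARG, was given for the final 2 weeks. The comparisons ask how fat of the strains differs, how the drug changes it in each, and how the depots differ. The 43 libraries held normalized values, of unknown depth, for 28644 transcripts of 22869 gene symbols. The 4 C57BL/6 iWAT libraries were coarser than the other 39. They held 467 to 679 distinct values against 1293 to 1865, and 32.1% to 37.7% of their transcripts lay at the floor of 1, against 15.2% to 27.2%. Levels are mean ± SD of normalized values, and the bracket after a gene gives its log2 fold change ± SE from limma. The labels do not say that replicates are separate animals, so p-values measure the spread between these samples.

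**Figure D1:**
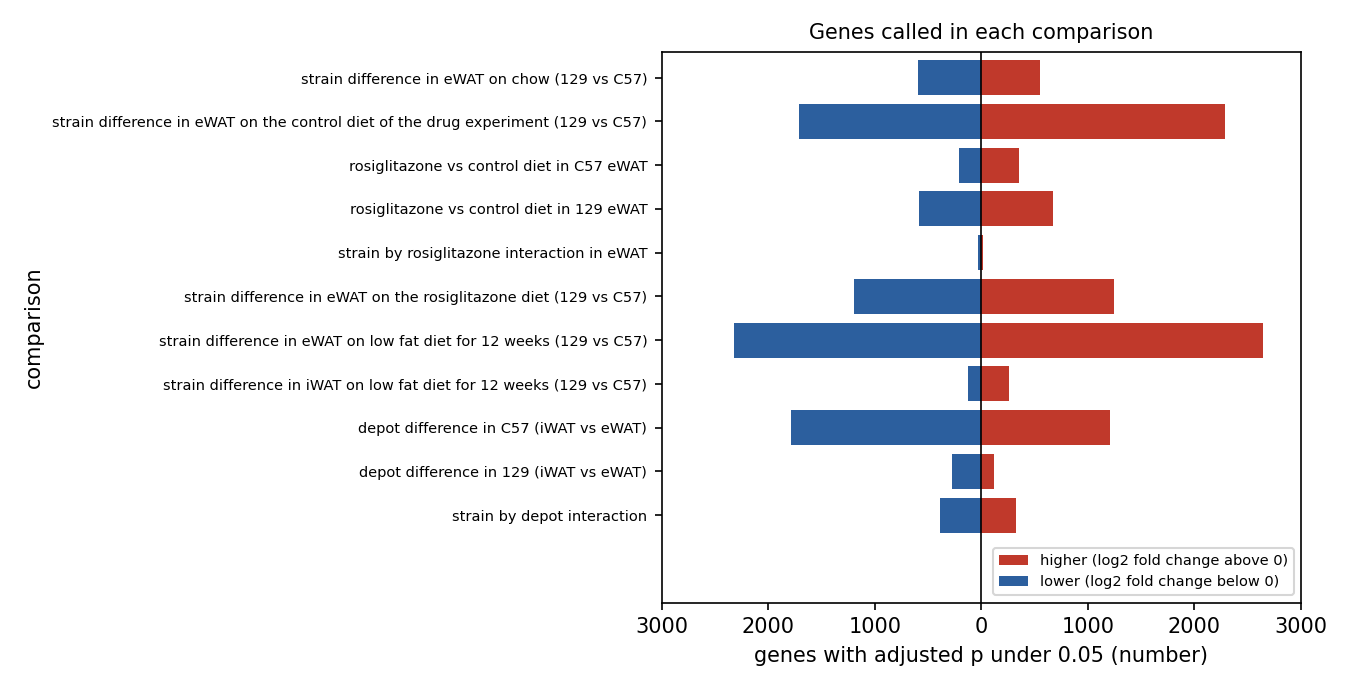
Number of genes with adjusted p under 0.05 in each comparison, with positive log2 fold changes drawn to the right and negative ones to the left. The counts run from 48 genes in the strain by rosiglitazone interaction to 4973 between the strains in eWAT after 12 weeks of low fat diet.

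On chow, the strains differed in the clock genes Cry1 and Per1, in the mitochondrial genes Nnt and Ndufa1, and in genes with values close to the floor in 1 strain. Nnt, the mitochondrial transhydrogenase, was 519 ± 116 in 129S1/SvImJ and 199.6 ± 19.4 in C57BL/6 (n = 5 each, log2 fold change 1.36 ± 0.14, adjusted p = 0.00221). Higher in 129S1/SvImJ were also Hal (6.23 ± 0.45), Gbp1 (4.94 ± 0.58) and Ndufa1 (0.72 ± 0.13), largest adjusted p = 0.0158, of which Hal encodes histidine ammonia lyase, Gbp1 an interferon-induced GTPase and Ndufa1 a complex I subunit. Lower were Trim12a (-5.16 ± 0.36), Trim30d (-4.01 ± 0.40), Pttg1 (-3.77 ± 0.26), Bub1b (-1.21 ± 0.21) and Iigp1 (-2.10 ± 0.36), largest adjusted p = 0.0161, of which Pttg1 and Bub1b act in mitosis and Iigp1 is interferon-induced. Rprl3 (7.47 ± 0.28) and Rpl29 (-5.09 ± 0.31) have near-identical copies in the genome, so their values are uncertain.

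limma called 1142 of 22869 genes on chow, 546 higher and 596 lower in 129S1/SvImJ. The circadian clock list was lower (3 of 17 members lower, 4 lower adjusted over the list alone, list adjusted p = 9.36e-04, adjusted p = 0.961 with an estimated correlation), with Cry1 (-0.68 ± 0.10) and Per1 (-1.09 ± 0.19), largest adjusted p = 0.0148. Endothelial genes were lower (none of 13 members called, 5 lower adjusted over the list alone, list adjusted p = 6.24e-05, adjusted p = 0.961 with an estimated correlation), while 3924 of all genes had an unadjusted p under 0.05. Endothelial Cdh5 (-1.29 ± 0.41, adjusted p = 0.138) and Kdr (-1.11 ± 0.36, adjusted p = 0.146) were not called with all libraries and were called without 129S1/SvImJ chow replicate 2 (-0.91, adjusted p = 0.0329, and -0.74, adjusted p = 0.00492). In that replicate the epididymis list lay 10.2 log2 units above the group median and the skin and glandular epithelium list 3.46 above it, and in replicate 1 the latter lay 2.65 above it. The epididymal lipocalin Lcn5 was 58238 in replicate 2 and 7 to 27 in the other 4, and Crisp1, also epididymal, averaged 14776 ± 20321. This SD is too small beside its mean for Crisp1 to be high in replicate 2 alone. Leaving out replicate 2 thus need not remove all epididymal RNA. Lcn5, Crisp1 (4.79 ± 2.71, adjusted p = 0.455), Pparg (-0.58 ± 0.67, adjusted p = 0.74), Adipoq (-0.38 ± 0.58, adjusted p = 0.831) and Ucp1 (1.55 ± 0.84, adjusted p = 0.427) were not called with all libraries.

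With all libraries, the epididymis list was called higher on chow (none of 14 members called, none adjusted over the list alone, list adjusted p = 0.0301, adjusted p = 0.961 with an estimated correlation). The skin and glandular epithelium list was higher (none of 15 members called, none adjusted over the list alone, list adjusted p = 0.0209, adjusted p = 0.961 with an estimated correlation). Mesothelial genes were higher (2 of 12 members higher, 2 higher adjusted over the list alone, list adjusted p = 0.0134, adjusted p = 0.961 with an estimated correlation). Adipocyte identity and lipid storage was lower (none of 22 members called, none adjusted over the list alone, list adjusted p = 0.0318, adjusted p = 0.961 with an estimated correlation). Insulin signalling and adipokines was lower (none of 19 members called, none adjusted over the list alone, list adjusted p = 0.0238, adjusted p = 0.961 with an estimated correlation). The interferon response was lower (1 of 22 members lower, 1 lower adjusted over the list alone, list adjusted p = 0.0256, adjusted p = 0.961 with an estimated correlation). Without 129S1/SvImJ replicates 1 and 2 the adipocyte (adjusted p = 0.704), insulin (adjusted p = 0.704), epididymis (adjusted p = 0.704), skin (adjusted p = 0.704) and interferon (adjusted p = 0.0849) lists were not called. The respiratory list (adjusted p = 1.24e-11) and fatty acid oxidation (adjusted p = 2.23e-04) were then called higher. Ucp1 was then called too (2.87, adjusted p = 0.00915), and with array weights Ucp1, Cdh5 and Kdr were called (adjusted p = 0.0177, 0.0184 and 0.0097). Pparg and Adipoq lay on the other side of 0 without replicate 2 (0.08, adjusted p = 0.931, and 0.19, adjusted p = 0.636). The number of called genes was 2597 without both libraries (1535 higher, 1062 lower) and 2564 without replicate 2 alone. It was 670 without 129S1/SvImJ replicate 3, and 655, 667 and 730 without C57BL/6 replicates 1, 2 and 3 in turn.

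On the control diet of the drug experiment, 129S1/SvImJ eWAT had more transcript of the mitochondrial genes Suclg1 and Cox5b and of the lipogenic and sterol genes Scd2, Pnpla3 and Pmvk than C57BL/6 eWAT, and less of Cdh5, Oasl2 and Rsad2. Suclg1, of the citrate cycle, was 625 ± 73.5 in 129S1/SvImJ and 279 ± 45.7 in C57BL/6 (n = 4 each, log2 fold change 1.17 ± 0.15, adjusted p = 1.60e-05). The lipid droplet gene Cidea was 112 ± 12.9 and 16 ± 4.55 (log2 fold change 2.76 ± 0.22, adjusted p = 2.28e-08). The complex IV subunit Cox5b (1.03 ± 0.17) and the lipogenic and sterol genes Scd2 (1.64 ± 0.35), Pnpla3 (1.38 ± 0.21) and Pmvk (1.22 ± 0.18) were higher (largest adjusted p = 0.00579). The sterol gene Nsdhl was 273 ± 88.9 and 93.8 ± 17.7 (adjusted p = 4.65e-05). The fatty acid transporter Slc27a1 (-1.83 ± 0.23), endothelial Cdh5 (-1.24 ± 0.19) and antiviral Oasl2 (-1.88 ± 0.30) and Rsad2 (-2.13 ± 0.36) were lower (largest adjusted p = 5.05e-04). Gbp2, also interferon-induced, was higher (0.88 ± 0.16, adjusted p = 5.93e-04).

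limma called 4006 genes in this comparison, 2290 higher and 1716 lower in 129S1/SvImJ. The respiratory chain and citrate cycle list was higher (34 of 44 members higher, 39 higher adjusted over the list alone, list adjusted p = 2.28e-14, adjusted p = 0.566 with an estimated correlation). Fatty acid synthesis was higher (8 of 19 members higher, 10 higher adjusted over the list alone, list adjusted p = 0.00232, adjusted p = 0.674 with an estimated correlation). Sterol synthesis and uptake was higher (10 of 21 members higher, 13 higher adjusted over the list alone, list adjusted p = 2.03e-04, adjusted p = 0.566 with an estimated correlation). Endothelial genes were lower (10 of 13 members lower, 12 lower adjusted over the list alone, list adjusted p = 4.68e-08, adjusted p = 0.566 with an estimated correlation). The interferon response was lower (1 of 22 members higher and 9 lower, 1 higher and 14 lower adjusted over the list alone, list adjusted p = 1.18e-05, adjusted p = 0.566 with an estimated correlation). Adipocyte genes went both ways (9 of 22 members higher and 3 lower, 9 higher and 4 lower adjusted over the list alone, list adjusted p = 0.392), with Agpat2 (1.00 ± 0.12) and Gpd1 (0.89 ± 0.12) higher (largest adjusted p = 3.00e-05) and the glycerol channel Aqp7 (-0.75 ± 0.10, adjusted p = 1.92e-05) lower. Nnt (1.02 ± 0.11) and Hal (5.31 ± 0.34) were higher again, and Trim12a (-4.82 ± 0.27) and the netrin receptor Unc5a (-4.10 ± 0.22) were lower (largest adjusted p = 1.02e-10). Pparg was higher by 0.35 (adjusted p = 0.0166), a call lost without C57BL/6 replicate 3 (adjusted p = 0.0529) and without 129S1/SvImJ replicate 3 or 4 (adjusted p = 0.0514 and 0.0527). Ucp1 was 21.5 ± 25.3 and 3.75 ± 0.5 (log2 fold change 1.62 ± 0.53, adjusted p = 0.0444). Its call was lost without C57BL/6 replicate 1, 2, 3 or 4 (adjusted p = 0.0769, 0.0891, 0.0826 and 0.1) and without 129S1/SvImJ replicate 2 or 3 (adjusted p = 0.0891 and 0.0955), and in a fit of these 8 libraries alone (adjusted p = 0.219). Adipoq (-0.11 ± 0.12, adjusted p = 0.617) was not called.

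After 12 weeks of low fat diet, 129S1/SvImJ eWAT had less Acly, Srebf1, Cyp51, Flt1, Kdr and Bst2 than C57BL/6 eWAT, and more Trem2 and Cidea. ATP citrate lyase, Acly, was 2143 ± 1261 in 129S1/SvImJ (n = 4) and 13016 ± 4228 in C57BL/6 (n = 5, log2 fold change -2.71 ± 0.39, adjusted p = 0.00308). The lipogenic genes Acss2 (-2.54 ± 0.34) and Thrsp (-1.72 ± 0.29), their regulator Srebf1 (-1.32 ± 0.19) and the sterol gene Cyp51 (-1.07 ± 0.18) were lower as well (largest adjusted p = 0.00628). So were the vascular growth factor receptors Flt1 (-1.60 ± 0.10) and Kdr (-1.24 ± 0.10) and antiviral Bst2 (-1.73 ± 0.12) and Usp18 (-0.97 ± 0.12), largest adjusted p = 0.00167. The macrophage receptor Trem2 was 426 ± 88.2 in 129S1/SvImJ against 34.6 ± 7.86 (log2 fold change 3.59 ± 0.21, adjusted p = 1.23e-04). Ucp1, the uncoupling protein of thermogenic fat, was 39 ± 17 in 129S1/SvImJ and at the floor of 1 in all 5 C57BL/6 libraries (log2 fold change 4.23 ± 0.26, adjusted p = 1.38e-04), so its fold change depends on the floor. Higher too were Cidea (2.55 ± 0.35), Pck1 (1.08 ± 0.10), Etfa (1.29 ± 0.09), Mmp2 (1.40 ± 0.15) and Thbs2 (2.06 ± 0.27), largest adjusted p = 0.00254.

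Of all genes 4973 were called here, 2646 higher and 2327 lower in 129S1/SvImJ. Library numbers do not run on between the strains here or in iWAT after this diet. Whether the strains were prepared together is not given in the sources used here. So strain and library series cannot be told apart in either depot. Endothelial genes were lower throughout (13 of 13 members lower, 13 lower adjusted over the list alone, list adjusted p = 5.34e-12, adjusted p = 0.223 with an estimated correlation). The interferon response was lower (13 of 22 members lower, 17 lower adjusted over the list alone, list adjusted p = 8.70e-09, adjusted p = 0.258 with an estimated correlation). Fatty acid synthesis was lower (12 of 19 members lower, 1 higher and 14 lower adjusted over the list alone, list adjusted p = 8.27e-07, adjusted p = 0.258 with an estimated correlation). Sterol synthesis was lower (2 of 21 members higher and 8 lower, 2 higher and 12 lower adjusted over the list alone, list adjusted p = 0.00655, adjusted p = 0.273 with an estimated correlation). Textbook PPARG agonist responsive genes were higher (9 of 21 members higher and 1 lower, 12 higher and 3 lower adjusted over the list alone, list adjusted p = 0.00655, adjusted p = 0.223 with an estimated correlation). Thermogenic genes were higher (9 of 24 members higher, 10 higher and 1 lower adjusted over the list alone, list adjusted p = 0.0087, adjusted p = 0.223 with an estimated correlation). Fatty acid oxidation was higher (6 of 21 members higher and 1 lower, 9 higher and 1 lower adjusted over the list alone, list adjusted p = 0.00655, adjusted p = 0.679 with an estimated correlation). Macrophage genes were not called as a list (6 of 24 members higher and 2 lower, 6 higher and 2 lower adjusted over the list alone, list adjusted p = 0.227), with Cx3cr1 (1.59 ± 0.26, adjusted p = 0.00555) among the higher. Skeletal muscle genes were not called as a list either (adjusted p = 0.403), and lay 5.67 above the group median in C57BL/6 replicate 3. Hal (6.42 ± 0.24), Nnt (0.96 ± 0.08), Foxo1 (1.18 ± 0.19) and Fabp4 (0.62 ± 0.10) were higher (largest adjusted p = 0.0053). The complex I subunit Ndufs5 (-4.80 ± 0.27, adjusted p = 8.84e-05) was lower. Unc5a (-5.15 ± 0.27), Trim12a (-5.31 ± 0.15) and the adipokine gene Retn (-1.39 ± 0.24) were lower (largest adjusted p = 0.00596), and Pparg (-0.02 ± 0.12, adjusted p = 1) and Adipoq (-0.05 ± 0.14, adjusted p = 0.969) were not called. Of 40 small nucleolar RNA genes, grouped after their values were seen, 28 were higher in 129S1/SvImJ and 0 lower, with a median of 1.88 (limma). On chow 0 were higher and 0 lower (median -0.07), on the control diet 0 and 6 (median -0.26), and in iWAT 3 and 0 (median 0.55).

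In iWAT after the same diet, the antiviral gene Bst2 was lower in 129S1/SvImJ, at 56.8 ± 5.12 against 204 ± 8.87 (n = 4 each, log2 fold change -1.83 ± 0.07, adjusted p = 8.60e-05). Hal (7.31 ± 0.71, adjusted p = 0.00894) was higher, and Unc5a (-4.56 ± 0.49) and Trim30d (-4.21 ± 0.37) were lower (largest adjusted p = 0.0135). The Trim30d call was lost without C57BL/6 replicate 2 (adjusted p = 0.0559), and the Unc5a call without C57BL/6 replicate 1, 2 or 3 (adjusted p = 0.0944, 0.0953 and 0.0895). The interferon response was lower (3 of 22 members lower, 9 lower adjusted over the list alone, list adjusted p = 1.34e-12, adjusted p = 0.226 with an estimated correlation). Fatty acid synthesis was lower (none of 19 members called, 5 lower adjusted over the list alone, list adjusted p = 3.07e-08, adjusted p = 0.226 with an estimated correlation). Sterol synthesis was lower (none of 21 members called, 3 lower adjusted over the list alone, list adjusted p = 2.39e-05, adjusted p = 0.333 with an estimated correlation). Acly (-1.84 ± 0.52, adjusted p = 0.204) and the malic enzyme Me1 (-1.63 ± 0.37, adjusted p = 0.121) were not called, and Acly was called without 129S1/SvImJ replicate 4 (-2.32, adjusted p = 0.0306). The immediate early list was lower (1 of 20 members lower, 1 lower adjusted over the list alone, list adjusted p = 0.0343, adjusted p = 0.438 with an estimated correlation). Insulin signalling and adipokines was lower (none of 19 members called, none adjusted over the list alone, list adjusted p = 0.0058, adjusted p = 0.333 with an estimated correlation). The cell cycle list was higher (none of 24 members called, 1 higher adjusted over the list alone, list adjusted p = 0.0183, adjusted p = 0.715 with an estimated correlation). Not called were Flt1 (-1.16 ± 0.26, adjusted p = 0.109), Fabp4 (0.79 ± 0.19, adjusted p = 0.134) and Nnt (0.50 ± 0.20, adjusted p = 0.386). Pparg (0.09 ± 0.23, adjusted p = 1), Adipoq (-0.13 ± 0.10, adjusted p = 0.75) and Ucp1 (1.57 ± 2.51, adjusted p = 0.985) were not called either. Among genes with a group mean of at least 20, Flt1 and Me1 were called (adjusted p = 0.0296 and 0.0262). Without the libraries set apart by marker lists, the immediate early (adjusted p = 0.103) and cell cycle (adjusted p = 0.945) lists were not called, and Acly, Me1 and Fabp4 were called (adjusted p = 0.0438, 0.0023 and 0.00596). limma called 387 genes, 259 higher and 128 lower, and 2875 at an unadjusted p under 0.05. The split was 80 higher and 164 lower among genes with a group mean of at least 20, 102 and 160 among genes with a value of at least 2, and 141 and 115 after a second quantile normalization. The excess of higher genes thus lay at low values. There the lowest value above the floor was 5 to 11 in C57BL/6 and 2 in 129S1/SvImJ. Leaving out C57BL/6 replicates 1 to 4 in turn gave 68, 68, 72 and 84 genes, and 129S1/SvImJ replicates 1 to 4 gave 171, 194, 188 and 137.

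Across the 4 drug-free strain comparisons 69 genes were called in the same direction, 26 higher and 43 lower in 129S1/SvImJ, where independent lists of these sizes share 0.0971. Hal (mean log2 fold change 6.31) was among the higher, and Trim12a (-5.19), Unc5a (-4.37) and Pttg1 (-3.99) among the lower. Without C57BL/6 iWAT replicates 1 to 4 in turn 25, 21, 27 and 29 were shared, and without 129S1/SvImJ iWAT replicates 1 to 4 36, 31, 32 and 27. In the 3 eWAT comparisons 332 were shared, 158 higher and 174 lower, where independent lists share 10.9. Over all genes, fold changes correlated with a Pearson r of 0.498 between chow and control diet, 0.46 between control diet and 12 weeks, and 0.417 between the depots, across genes that are not independent replicates.

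In C57BL/6 eWAT, rosiglitazone raised genes of fat oxidation, sterol synthesis and lipid storage, and lowered collagen IV genes. Sptlc3, a subunit of serine palmitoyltransferase, was 70.8 ± 32.2 with the drug and 3.25 ± 1.5 without (n = 4 each, log2 fold change 4.07 ± 0.34, adjusted p = 9.54e-07). The proton channel gene Otop1 was 109.8 ± 39.5 and 7.75 ± 3.4 (log2 fold change 3.65 ± 0.46, adjusted p = 4.44e-04). Cpt1b (1.83 ± 0.27), which admits fatty acids to mitochondria, Acsl1 (0.97 ± 0.13), which activates them, and the citrate cycle gene Idh3a (0.86 ± 0.12) rose (largest adjusted p = 0.00106). Clstn3 (1.92 ± 0.21), Arxes1 (1.88 ± 0.17), Elovl3 (2.74 ± 0.42), Cidea (1.79 ± 0.22) and Pdk4 (1.29 ± 0.25) rose too. So did the sterol genes Insig1 (1.69 ± 0.24) and Lss (1.45 ± 0.17) and the malic enzyme Me1 (1.34 ± 0.26), largest adjusted p = 0.0111. Gpd1, which makes glycerol 3-phosphate, rose from 4634 ± 584 to 11620.2 ± 1619.5 (log2 fold change 1.32 ± 0.12, adjusted p = 2.19e-06). Serpina3n (-1.86 ± 0.11), complement C6 (-1.94 ± 0.34), Col4a1 (-0.82 ± 0.12) and Col4a2 (-0.76 ± 0.10) fell (largest adjusted p = 0.0048). Not called were Pparg (0.03 ± 0.10, adjusted p = 0.988), Adipoq (0.07 ± 0.12, adjusted p = 0.876), Angptl4 (-0.03 ± 0.14, adjusted p = 1) and Ucp1 (0.07 ± 0.53, adjusted p = 1), with Ucp1 at 4 ± 0.816 and 3.75 ± 0.5.

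The count for C57BL/6 was 556 genes, 350 higher and 206 lower with the drug. Fatty acid oxidation rose (15 of 21 members higher, 20 higher and 1 lower adjusted over the list alone, list adjusted p = 4.17e-18, and adjusted p = 0.039 with an estimated correlation). Textbook PPARG agonist responsive genes rose (9 of 21 members higher, 11 higher adjusted over the list alone, list adjusted p = 2.85e-07, and adjusted p = 0.039 with an estimated correlation). Thermogenic genes rose (6 of 24 members higher, 6 higher adjusted over the list alone, list adjusted p = 4.56e-05, and adjusted p = 0.039 with an estimated correlation). Sterol synthesis rose (9 of 21 members higher, 14 higher adjusted over the list alone, list adjusted p = 8.83e-12, and adjusted p = 0.039 with an estimated correlation). The adipocyte list rose (6 of 22 members higher, 8 higher and 1 lower adjusted over the list alone, list adjusted p = 4.91e-04, and adjusted p = 0.039 with an estimated correlation). The respiratory list rose (14 of 44 members higher, 35 higher adjusted over the list alone, list adjusted p = 6.98e-22, adjusted p = 0.181 with an estimated correlation). Fatty acid synthesis rose (3 of 19 members higher, 9 higher and 1 lower adjusted over the list alone, list adjusted p = 9.79e-06, adjusted p = 0.208 with an estimated correlation). Extracellular matrix fell (3 of 27 members lower, 7 lower adjusted over the list alone, list adjusted p = 1.51e-07, adjusted p = 0.226 with an estimated correlation). Macrophage genes fell (1 of 24 members lower, 4 lower adjusted over the list alone, list adjusted p = 2.81e-05, adjusted p = 0.434 with an estimated correlation). Endothelial genes fell (none of 13 members called, 6 lower adjusted over the list alone, list adjusted p = 6.02e-04, adjusted p = 0.434 with an estimated correlation). Erythroid genes fell (none of 7 members called, 2 lower adjusted over the list alone, list adjusted p = 3.44e-04, adjusted p = 0.208 with an estimated correlation). A fit of these 8 libraries alone called 73 genes, without Elovl3, Pdk4, Insig1, Me1, C6, Col4a1 or Col4a2. The count was 350 without C57BL/6 control replicate 2, and 326 and 275 without C57BL/6 rosiglitazone replicates 3 and 4.

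In 129S1/SvImJ eWAT, rosiglitazone raised Ucp1 and the oxidation genes Acsl1, Etfa and Hadha, and lowered Elovl6, Thrsp and Fads1. Ucp1 was 412 ± 211 with the drug and 21.5 ± 25.3 without (n = 4 each, log2 fold change 4.68 ± 0.53, adjusted p = 3.31e-05), with 241 to 680 against 4 to 59 in single libraries. The fatty acid elongase Elovl3 (4.81 ± 0.42, adjusted p = 5.35e-07) rose, and so did Sptlc3 (3.54 ± 0.34), Otop1 (3.45 ± 0.46), Chchd10 (3.33 ± 0.23), Cpt1b (3.19 ± 0.27), Pdk4 (2.72 ± 0.25) and Cidea (2.31 ± 0.22), largest adjusted p = 2.50e-04. The lipid droplet coat gene Plin5 (2.13 ± 0.23), the oxidation genes Acsl1 (1.42 ± 0.13), Etfa (1.15 ± 0.10) and Hadha (1.29 ± 0.12) rose as well (largest adjusted p = 1.01e-05). The PPARG targets Fabp4 (0.86 ± 0.12) and Angptl4 (0.86 ± 0.14) rose (largest adjusted p = 3.98e-04). Elovl6 (-2.38 ± 0.40), Thrsp (-1.44 ± 0.26) and Fads1 (-0.94 ± 0.15), of fatty acid synthesis, fell (largest adjusted p = 0.00387). So did the adipokine gene Retn (-1.47 ± 0.24), the acute phase gene Orm3 (-3.38 ± 0.28), the peptidase gene Enpep (-2.46 ± 0.31), Lyz1 (-1.29 ± 0.19) and Col4a1 (-0.59 ± 0.12), largest adjusted p = 0.0053. Nnt (-1.17 ± 0.11) and Pparg (-0.49 ± 0.10) itself fell (largest adjusted p = 0.00408), and Adipoq (0.04 ± 0.12, adjusted p = 0.961) was not called. A fit of these 8 libraries alone did not call Thrsp, Angptl4 or Col4a1 (adjusted p = 0.0556, 0.0594 and 0.0741).

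The count for 129S1/SvImJ was 1261 genes, 676 higher and 585 lower, or 788 without 129S1/SvImJ control replicate 4. Fatty acid oxidation rose (20 of 21 members higher, 20 higher adjusted over the list alone, list adjusted p = 1.20e-36, and adjusted p = 0.00534 with an estimated correlation). Textbook PPARG agonist responsive genes rose (14 of 21 members higher, 18 higher adjusted over the list alone, list adjusted p = 1.20e-24, and adjusted p = 5.47e-04 with an estimated correlation). Thermogenic genes rose (12 of 24 members higher, 14 higher adjusted over the list alone, list adjusted p = 1.16e-13, and adjusted p = 6.63e-04 with an estimated correlation). The respiratory list rose (25 of 44 members higher, 38 higher adjusted over the list alone, list adjusted p = 3.04e-27, adjusted p = 0.175 with an estimated correlation). Fatty acid synthesis fell (3 of 19 members lower, 3 higher and 8 lower adjusted over the list alone, list adjusted p = 0.00439, adjusted p = 0.543 with an estimated correlation). The mesothelial list was lower (none of 12 members called, 1 lower adjusted over the list alone, list adjusted p = 0.00205, adjusted p = 0.652 with an estimated correlation). The cell cycle list was higher (1 of 24 members higher, 1 higher adjusted over the list alone, list adjusted p = 0.00409, adjusted p = 0.445 with an estimated correlation).

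**Figure D2:**
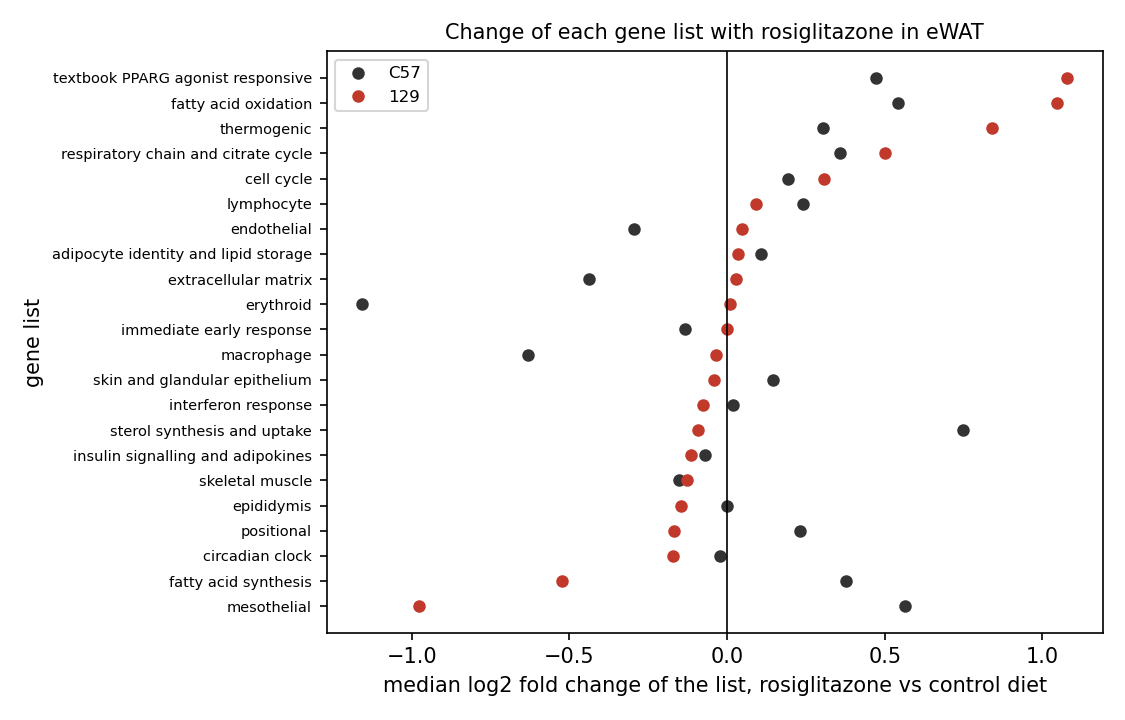
Median log2 fold change of each gene list between rosiglitazone and control diet in eWAT, with dark points for C57BL/6 and red points for 129S1/SvImJ. Textbook PPARG agonist responsive genes had a median of 0.47 in C57BL/6 and 1.08 in 129S1/SvImJ, and fatty acid synthesis 0.38 and -0.52.

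Whether the drug acted differently in the strains was tested as an interaction, where a positive value is a larger rise or smaller fall in 129S1/SvImJ. Ucp1 (4.62 ± 0.75, adjusted p = 0.0165) was positive, a call lost without C57BL/6 control replicate 1 (adjusted p = 0.0505) or C57BL/6 rosiglitazone replicate 3 or 4 (adjusted p = 0.0666 and 0.0523). BC090627 (1.14 ± 0.19, adjusted p = 0.0123) was positive too. Sorl1 (-1.83 ± 0.26), Tlcd2 (-1.78 ± 0.27) and Tuba1a (-1.70 ± 0.26) were negative, with a largest adjusted p of 0.0103. The sterol gene Nsdhl (-1.67 ± 0.29, adjusted p = 0.0165) was negative, but not called without 129S1/SvImJ control replicate 1 (adjusted p = 0.0506) or C57BL/6 rosiglitazone replicate 3 (adjusted p = 0.053). Ptges (-1.88 ± 0.31) lost its call without 129S1/SvImJ control replicate 1 (adjusted p = 0.0506) or 129S1/SvImJ rosiglitazone replicate 2 (adjusted p = 0.0578), and Gpd1 (-0.96 ± 0.17) lost its call without C57BL/6 rosiglitazone replicate 3 (adjusted p = 0.0671) or after a second quantile normalization (adjusted p = 0.0654). Not called were Elovl3 (2.07 ± 0.60, adjusted p = 0.174), Plin5 (1.26 ± 0.32, adjusted p = 0.121), Elovl6 (-2.52 ± 0.57, adjusted p = 0.111) and Pparg (-0.51 ± 0.14, adjusted p = 0.146). Pdk4 (1.43 ± 0.35, adjusted p = 0.125) and Etfa (0.69 ± 0.15, adjusted p = 0.0523) were not called with all libraries and were called without C57BL/6 rosiglitazone replicate 1 (adjusted p = 0.00501 and 0.00946). Angptl4 (0.89 ± 0.19, adjusted p = 0.06) was called without 129S1/SvImJ control replicate 2 (adjusted p = 0.00987), C57BL/6 rosiglitazone replicate 1 (adjusted p = 0.0322) or 129S1/SvImJ rosiglitazone replicate 3 (adjusted p = 0.0438). Nnt (-0.71 ± 0.16, adjusted p = 0.0633) was called without C57BL/6 control replicate 4 (adjusted p = 0.023). Among genes with a group mean of at least 20, Etfa and Nnt were called (adjusted p = 0.0336 and 0.0369), and with array weights Angptl4 too (adjusted p = 0.0447).

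limma called 48 genes for the interaction, 17 positive and 31 negative, and 2265 at an unadjusted p under 0.05. Textbook PPARG agonist responsive genes responded more in 129S1/SvImJ (1 of 21 members positive, 12 positive adjusted over the list alone, list adjusted p = 8.55e-13, and adjusted p = 0.0107 with an estimated correlation). Thermogenic genes responded more in 129S1/SvImJ (1 of 24 members positive, 7 positive adjusted over the list alone, list adjusted p = 6.82e-06, and adjusted p = 0.0287 with an estimated correlation). The member called in both of these lists was Ucp1, and the lists share other members too. Fatty acid oxidation responded more in 129S1/SvImJ (none of 21 members called, 17 positive adjusted over the list alone, list adjusted p = 3.57e-15, adjusted p = 0.0612 with an estimated correlation). The sterol list was negative (4 of 21 members negative, 13 negative adjusted over the list alone, list adjusted p = 1.64e-10, adjusted p = 0.0612 with an estimated correlation). Fatty acid synthesis was negative (none of 19 members called, 11 negative adjusted over the list alone, list adjusted p = 8.39e-11, adjusted p = 0.0612 with an estimated correlation). In all 11 lists were called, 2 of them also with an estimated correlation. The other 6 had no member called. The positive ones were respiratory (adjusted p = 0.0131, adjusted p = 0.665 with an estimated correlation), extracellular matrix (adjusted p = 9.80e-05, adjusted p = 0.431 with an estimated correlation), endothelial (adjusted p = 0.00413, adjusted p = 0.56 with an estimated correlation) and erythroid (adjusted p = 0.00118, adjusted p = 0.305 with an estimated correlation), and the negative ones mesothelial (adjusted p = 2.39e-05, adjusted p = 0.431 with an estimated correlation) and positional (adjusted p = 0.0133, adjusted p = 0.123 with an estimated correlation). The gene count was 21, 27 and 76 without C57BL/6 control replicates 1, 2 and 4 in turn, 18, 29, 25 and 23 without 129S1/SvImJ control replicates 1 to 4, 113, 14 and 25 without C57BL/6 rosiglitazone replicates 1, 3 and 4, and 22 and 24 without 129S1/SvImJ rosiglitazone replicates 1 and 2.

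**Figure D3:**
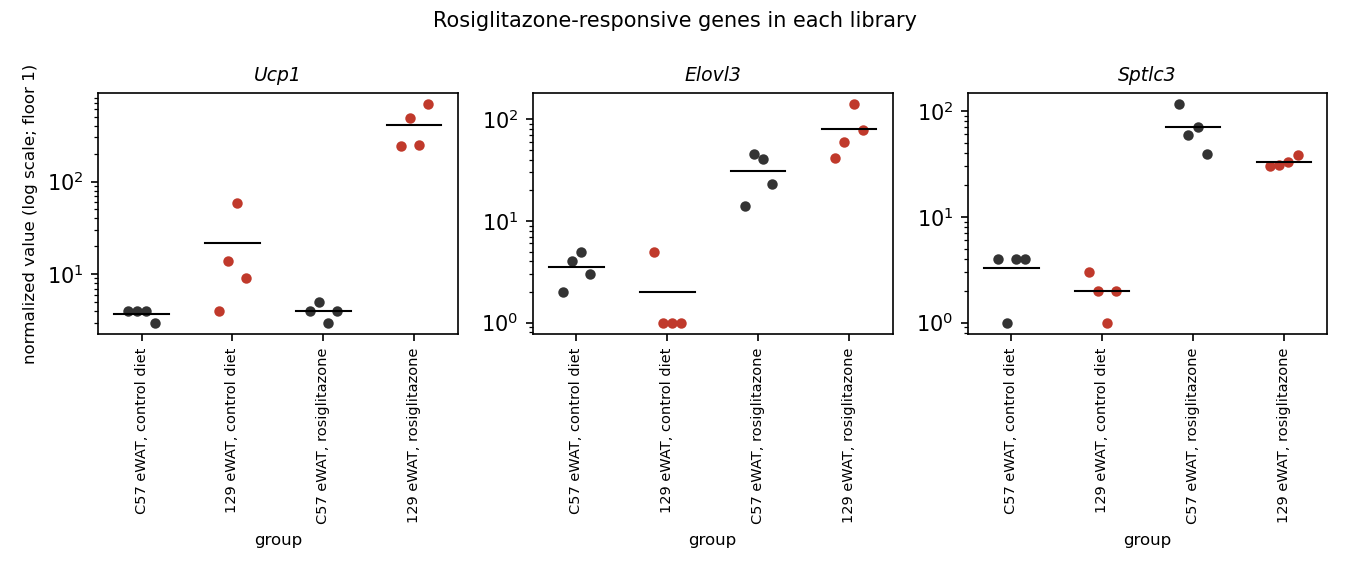
Normalized values of Ucp1, Elovl3 and Sptlc3 in each eWAT library of the drug experiment on a log scale, with 1 point per library and a line at the mean of the 4 libraries of a group. Ucp1 lay between 241 and 680 in the 129S1/SvImJ rosiglitazone libraries and at 5 or below in the C57BL/6 libraries.

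Both strains shared 275 drug-responsive genes, 171 higher and 104 lower, where independent lists share 15.6, and 5 genes were called in opposite directions. Elovl3 (mean log2 fold change 3.77) and Otop1 (3.55) were among those raised, and Orm3 (-2.37) and C6 (-1.99) among those lowered. The shared count was 181 and 158 without C57BL/6 rosiglitazone replicates 3 and 4 in turn. Of the 1537 genes called in either strain, 1282 (83.4%) moved the same way. Across all genes, which are not independent replicates, Pearson r was 0.283. Of the same 1537 genes the absolute fold change was larger in 129S1/SvImJ for 1154 (75.1%), with medians of 0.60 in 129S1/SvImJ and 0.37 in C57BL/6. Genes entered this set by calls in either strain, and this share was not tested.

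On the rosiglitazone diet, 129S1/SvImJ eWAT had more Ucp1, Cidea, Cox7a1 and Suclg1 than C57BL/6 eWAT, and less Rsad2, Bst2 and Eng. Ucp1 was 412 ± 211 in 129S1/SvImJ and 4 ± 0.816 in C57BL/6 (n = 4 each, log2 fold change 6.24 ± 0.53, adjusted p = 6.70e-07). Cidea was 585 ± 195 and 57 ± 9.59 (log2 fold change 3.28 ± 0.22, adjusted p = 1.61e-09). Higher were the respiratory and oxidation genes Cox7a1 (2.40 ± 0.34), Suclg1 (1.32 ± 0.15) and Acaa2 (1.36 ± 0.15), and Trem2 (3.29 ± 0.50), Col5a2 (1.46 ± 0.15) and Mmp2 (1.69 ± 0.20), largest adjusted p = 8.70e-04. Antiviral Rsad2 (-1.90 ± 0.36) and Bst2 (-1.46 ± 0.27) and endothelial Eng (-0.79 ± 0.15) were lower (largest adjusted p = 0.0019), and Nnt (0.31 ± 0.11, adjusted p = 0.0819) and Pparg (-0.16 ± 0.10, adjusted p = 0.368) were not called. limma called 2443 genes, 1247 higher and 1196 lower, or 1614 without 129S1/SvImJ rosiglitazone replicate 1. A fit of these 8 libraries alone called 1407, with Nnt (adjusted p = 0.018) and without Rsad2, Bst2 or Eng. The respiratory list was higher (37 of 44 members higher, 41 higher adjusted over the list alone, list adjusted p = 8.43e-26, adjusted p = 0.167 with an estimated correlation). Fatty acid oxidation was higher (14 of 21 members higher, 14 higher adjusted over the list alone, list adjusted p = 2.54e-10, adjusted p = 0.167 with an estimated correlation). Thermogenic genes were higher (9 of 24 members higher, 10 higher adjusted over the list alone, list adjusted p = 8.49e-06, adjusted p = 0.0612 with an estimated correlation). Textbook PPARG agonist responsive genes were higher (10 of 21 members higher and 1 lower, 12 higher and 4 lower adjusted over the list alone, list adjusted p = 6.79e-04, adjusted p = 0.167 with an estimated correlation). Extracellular matrix was higher (6 of 27 members higher, 13 higher adjusted over the list alone, list adjusted p = 1.83e-06, adjusted p = 0.437 with an estimated correlation). The interferon response was lower (11 of 22 members lower, 16 lower adjusted over the list alone, list adjusted p = 1.95e-09, adjusted p = 0.12 with an estimated correlation). Endothelial genes were lower (5 of 13 members lower, 7 lower adjusted over the list alone, list adjusted p = 1.24e-04, adjusted p = 0.506 with an estimated correlation). Fatty acid synthesis was lower (2 of 19 members lower, 2 lower adjusted over the list alone, list adjusted p = 0.00473, adjusted p = 0.514 with an estimated correlation).

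Between depots in C57BL/6 after 12 weeks of low fat diet, iWAT had less of the mesothelial genes Msln, Upk3b and Wt1 than eWAT, and more Prdm16, Col1a1 and Hoxc10. Depot and experiment coincide here, and the tables of both depots were normalized together. Mesothelin, Msln, was at the floor of 1 in all 4 iWAT libraries and 496 ± 84.7 in eWAT (n = 5, log2 fold change -7.94 ± 0.09, adjusted p = 2.14e-15), a fold change that depends on the floor. Other genes of the mesothelium were lower too: Upk3b (-8.43 ± 0.30), Upk1b (-6.91 ± 0.13), Wt1 (-5.43 ± 0.11) and Lrp2 (-7.31 ± 0.23), largest adjusted p = 9.17e-10. The developmental regulators Hoxc10 (5.11 ± 0.31), Tbx15 (4.57 ± 0.49), Hoxa10 (4.27 ± 0.20) and Shox2 (3.47 ± 0.21) were higher in iWAT (largest adjusted p = 5.25e-05) and Tcf21 (-2.87 ± 0.14, adjusted p = 3.24e-08) was lower. Prdm16, a regulator of thermogenic fat, was 215 ± 53.9 against 49.6 ± 6.66 (log2 fold change 2.07 ± 0.26, adjusted p = 2.33e-04), with Otop1 (3.96 ± 0.59), Ppargc1a (1.97 ± 0.29) and Cidea (3.74 ± 0.70), largest adjusted p = 0.00344. Ucp1 (4.73 ± 1.64, adjusted p = 0.0769), at 569 ± 1028 in iWAT, was not called, and was called without C57BL/6 iWAT replicate 2 (6.31, adjusted p = 0.0152), with array weights (adjusted p = 0.0493) and among genes with a group mean of at least 20 (adjusted p = 0.0229). The matrix genes Col1a1 (2.47 ± 0.20), Mmp2 (2.28 ± 0.16) and Mmp3 (5.35 ± 0.30), Cox5b (1.57 ± 0.21), Foxo1 (1.04 ± 0.17) and Irs1 (0.91 ± 0.17) were higher (largest adjusted p = 0.00353). Pparg (-0.30 ± 0.17, adjusted p = 0.321) and Adipoq (-0.13 ± 0.12, adjusted p = 0.617) were not called, and a fit of both groups alone called Adipoq (adjusted p = 0.0381).

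In this comparison 2992 genes were called, 1206 higher and 1786 lower in iWAT. Mesothelial genes were lower (11 of 12 members lower, 11 lower adjusted over the list alone, list adjusted p = 4.12e-31, and adjusted p = 1.62e-04 with an estimated correlation). Thermogenic genes were higher (7 of 24 members higher, 11 higher adjusted over the list alone, list adjusted p = 4.64e-09, adjusted p = 0.488 with an estimated correlation). Extracellular matrix was higher (11 of 27 members higher and 1 lower, 13 higher and 1 lower adjusted over the list alone, list adjusted p = 3.25e-07, adjusted p = 0.503 with an estimated correlation). Fatty acid oxidation was higher (4 of 21 members higher, 4 higher adjusted over the list alone, list adjusted p = 2.45e-04, adjusted p = 0.653 with an estimated correlation). The respiratory list was higher (7 of 44 members higher and 1 lower, 8 higher and 1 lower adjusted over the list alone, list adjusted p = 0.00854, adjusted p = 0.885 with an estimated correlation). The positional list was higher (7 of 20 members higher and 3 lower, 9 higher and 3 lower adjusted over the list alone, list adjusted p = 0.0091, adjusted p = 0.393 with an estimated correlation). Erythroid genes were lower (3 of 7 members lower, 3 lower adjusted over the list alone, list adjusted p = 0.0043, adjusted p = 0.503 with an estimated correlation). Endothelial genes were lower (3 of 13 members lower, 6 lower adjusted over the list alone, list adjusted p = 0.0091, adjusted p = 0.653 with an estimated correlation). The lymphocyte list was higher (none of 23 members called, none adjusted over the list alone, list adjusted p = 0.0379, adjusted p = 0.885 with an estimated correlation) and lay 4.31 above the group median in C57BL/6 iWAT replicate 4. Without the libraries set apart the lymphocyte (adjusted p = 0.696) and respiratory (adjusted p = 0.161) lists were not called. Of the small nucleolar RNA genes 13 were higher in iWAT (median 0.86). Mtrnr2l was 118 ± 13.8 in iWAT and 1 ± 0 in eWAT (log2 fold change 5.89 ± 0.17, adjusted p = 7.24e-11).

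In 129S1/SvImJ the depots differed in the mesothelial genes Upk3b and Msln and in the regulators Tbx15 and Hoxc10. Upk3b was 2 ± 0.816 in iWAT and 550.5 ± 85.9 in eWAT (n = 4 each, log2 fold change -7.55 ± 0.32, adjusted p = 5.63e-09). Lower in iWAT too were Msln (-7.23 ± 0.10), Lrp2 (-7.06 ± 0.25), Wt1 (-5.36 ± 0.11) and Pkhd1l1 (-5.66 ± 0.25), largest adjusted p = 7.72e-09. Tbx15 (4.50 ± 0.51), Hoxa10 (4.19 ± 0.21), Hoxc10 (3.99 ± 0.32) and Shox2 (3.39 ± 0.22) were higher (largest adjusted p = 2.40e-04), as were Mmp3 (3.33 ± 0.31) and Col1a1 (1.47 ± 0.21), largest adjusted p = 0.00158. Tcf21 (-3.50 ± 0.15) and Nnt (-0.93 ± 0.15) were lower (largest adjusted p = 0.00509). Prdm16 (1.38 ± 0.28, adjusted p = 0.0213) was higher, but not called without 129S1/SvImJ eWAT replicate 2, 3 or 4 (adjusted p = 0.0739, 0.0689 and 0.065) or the libraries set apart (adjusted p = 0.0902). limma called 393 genes, 120 higher and 273 lower, 231 without 129S1/SvImJ iWAT replicate 4, and 101 higher and 146 lower without the libraries set apart by marker lists. A fit of these 8 libraries alone called 211, without Prdm16, Col1a1 or Nnt. Mesothelial genes were lower (11 of 12 members lower, 11 lower adjusted over the list alone, list adjusted p = 1.16e-48, and adjusted p = 1.35e-05 with an estimated correlation). Thermogenic genes were higher (3 of 24 members higher, 4 higher and 1 lower adjusted over the list alone, list adjusted p = 6.48e-04, adjusted p = 0.48 with an estimated correlation). The positional list was not called, and its members went both ways (6 of 20 members higher and 3 lower, 7 higher and 6 lower adjusted over the list alone, list adjusted p = 0.155). Lymphocyte genes had a median of 2.71 (none of 23 members called, none adjusted over the list alone, list adjusted p = 3.08e-09, adjusted p = 0.48 with an estimated correlation), with 3036 of all genes at an unadjusted p under 0.05. They lay 3.32 and 2.02 above the group median in 129S1/SvImJ iWAT replicates 1 and 4, and were not called without the libraries set apart (adjusted p = 0.503). Ucp1 (2.07 ± 1.73, adjusted p = 0.655), Pparg (-0.19 ± 0.18, adjusted p = 0.723) and Adipoq (-0.20 ± 0.13, adjusted p = 0.52) were not called, with Ucp1 at 647 ± 1163 in iWAT. Depot differences were shared by both strains for 230 genes, 49 higher and 181 lower in iWAT, where independent lists share 27.6, and 11 were called in opposite directions.

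**Figure D4:**
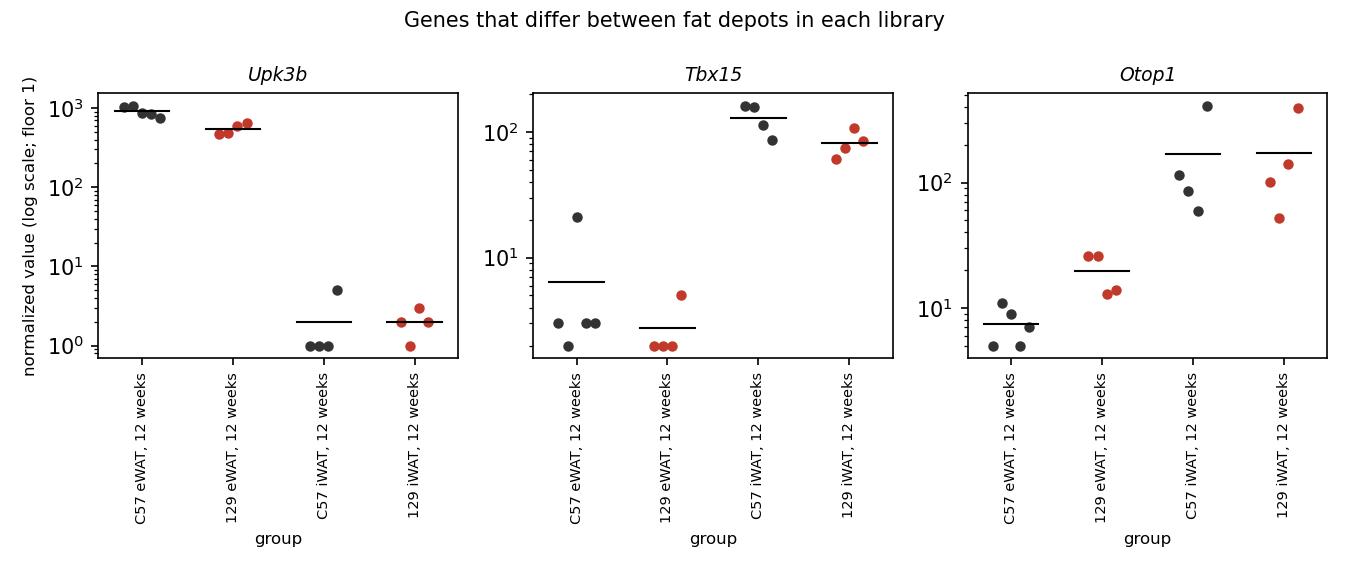
Normalized values of Upk3b, Tbx15 and Otop1 in each library after 12 weeks of low fat diet on a log scale, with 1 point per library and a line at the group mean (5 C57BL/6 eWAT libraries, 4 in each other group). Upk3b averaged 550.5 in 129S1/SvImJ eWAT and 2 in 129S1/SvImJ iWAT.

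The interaction of strain and depot asks where the depot difference itself differed, a positive value being a larger rise or smaller fall from eWAT to iWAT in 129S1/SvImJ. Endothelial Pecam1 (1.37 ± 0.25, adjusted p = 0.014) was positive, and the matrix proteases Mmp2 (-1.73 ± 0.23) and Mmp3 (-2.03 ± 0.43), osteopontin, Spp1 (-3.41 ± 0.66), Etfa (-1.49 ± 0.29) and Foxo1 (-1.16 ± 0.24) were negative (largest adjusted p = 0.0257). Mmp2 was 214 ± 32.6 in C57BL/6 eWAT, 1036 ± 78.3 in C57BL/6 iWAT, 568 ± 87.9 in 129S1/SvImJ eWAT and 845 ± 195 in 129S1/SvImJ iWAT. Slpi (4.46 ± 0.85), Serpina3b (4.01 ± 0.42) and Tekt1 (3.48 ± 0.65) were positive, with C57BL/6 iWAT means of 2, 1 and 1, so their size depends on the floor. Mtrnr2l (-5.93 ± 0.24), Snord22 (-4.24 ± 0.63) and Snora26 (-3.05 ± 0.53) were negative (largest adjusted p = 0.011), Snord22 at 34.4 ± 16.5 in C57BL/6 eWAT and 751 ± 411 in C57BL/6 iWAT. limma called 717 genes, 328 positive and 389 negative. Each group has its own series of library numbers, so library series cannot be told apart from this interaction. Endothelial genes were positive (2 of 13 members positive, 10 positive adjusted over the list alone, list adjusted p = 3.91e-07, adjusted p = 0.584 with an estimated correlation). Mesothelial genes were positive (4 of 12 members positive, 5 positive and 1 negative adjusted over the list alone, list adjusted p = 0.0148, adjusted p = 0.584 with an estimated correlation). Msln and Upk3b lay at or near the floor in C57BL/6 iWAT, so this call may depend on it. Extracellular matrix was negative (3 of 27 members negative, 5 negative adjusted over the list alone, list adjusted p = 3.31e-05, adjusted p = 0.584 with an estimated correlation). The thermogenic list was negative (2 of 24 members negative, 2 negative adjusted over the list alone, list adjusted p = 0.0106, adjusted p = 0.717 with an estimated correlation). Ucp1 (-2.66 ± 2.38, adjusted p = 0.658) was not called. Pecam1, Mmp3 and Spp1 were not called without the libraries set apart by marker lists (adjusted p = 0.0632, 0.112 and 0.0662), nor was Mmp3 with array weights (adjusted p = 0.0869). The gene count was 456, 476, 460 and 424 without C57BL/6 eWAT replicates 1, 2, 3 and 5 in turn, 463 without 129S1/SvImJ eWAT replicate 3 and 1122 without C57BL/6 iWAT replicate 4.

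The authors' deposited table of log2 fold changes was set against the values computed here, after its strain ratios, C57BL/6 over 129S1/SvImJ, had been turned to 129S1/SvImJ over C57BL/6. Pearson r over all genes lay between 0.843 and 0.952 in 5 of the 6 comparisons it gives. In the iWAT strain comparison it was 0.372, and 0.936 over the 12203 genes with a mean of at least 20. Of the 387 genes called here, 247 had the same sign in the authors' deposited table.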

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

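The tests of other splits of the libraries and of short RNAs of other classes were set before their results were seen, and the other tests weighed here were chosen after the result was seen.

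Epididymal Lcn5 was abundant in 1 chow library, 129S1/SvImJ replicate 2, where the epididymis list lay 10.2 log2 units above the group median. The adipocyte list of this library lay below the lowest of replicates 3 to 5 (-2.76), which is consistent with RNA from epididymis in the sampled fat. A library of the wrong strain was tested by asking whether strain genes lay nearer the other 129S1/SvImJ chow libraries than the C57BL/6 mean. They did for 83.4% of 332 genes chosen with the chow comparison, and for 73.8% of 107 genes chosen without it, where single C57BL/6 chow libraries reached 3.74% to 10.3% and the other 129S1/SvImJ ones 92.5% to 99.1%, which argues against a wrong label, although replicate 2 reached 58.7% of those higher in 129S1/SvImJ and 85.2% of those lower. No biological explanation was tested.

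Small nucleolar RNA genes, which sit within introns of other genes, were low in C57BL/6 eWAT after 12 weeks of low fat diet, with a mean log2 level of 3.33 against 5.28 in 129S1/SvImJ eWAT and 4.34 in C57BL/6 iWAT. The higher of the strain medians on chow and on the control diet was -0.0684, which argues against a constant strain difference, and on that control diet, also low fat, it was -0.26. Genes of other short RNA classes had a median of 0.0421 over 54 genes (SD 1.16), with 13 higher and 10 lower, which argues against a loss of all short RNAs alike. The highest share of transcripts at the floor in these libraries was 24.6%, under the lowest of 32.1% in C57BL/6 iWAT, which argues against low depth. An effect of age, experiment or library preparation in this group, or of the authors' normalization, was not tested and stays open.

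Ucp1 rose with rosiglitazone in 129S1/SvImJ eWAT and was not called in C57BL/6. Its interaction was 4.62 on the log2 scale (adjusted p = 0.0165), a call lost without some single libraries, as given above. Positional genes higher in iWAT had a median change of -0.17 with the drug in 129S1/SvImJ (6 genes, SD 0.32), which argues against inguinal fat in these libraries. Ucp1 reached 2108 and 156 in 2 of 4 C57BL/6 iWAT libraries, normalized apart, against at most 5 in C57BL/6 eWAT of the drug experiment, and mm9 is a C57BL/6 genome, which argues against a strain variant that hides C57BL/6 Ucp1 from the reference. For brown fat in the rosiglitazone 129S1/SvImJ libraries, Zic1, a brown fat marker, was at most 1 there and at most 4 in any library, so brown fat cannot be told apart. A difference between the strains in the thermogenic response to the drug stays among the open explanations beside brown fat, on 4 libraries per group. The thermogenic list was called in the interaction (camera, adjusted p = 6.82e-06, and adjusted p = 0.0287 with an estimated correlation). That list holds Ucp1, its only member called there, so it is not separate evidence for this explanation.

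Other splits of the libraries of both groups, fitted alone, were set against the real split by the number of genes called. Over 35 splits, the highest count of another split against the real one was 17 against 2966 genes for the strains on control diet, 19 against 73 for the drug in C57BL/6, 25 against 960 for the drug in 129S1/SvImJ, 34 against 1407 for the strains on the drug, 2 against 387 for the strains in iWAT and 9 against 211 for the depots in 129S1/SvImJ. Over 100 splits it was 105 against 1142 on chow, 9 against 4973 between the strains in eWAT after 12 weeks and 68 against 2794 for the depots in C57BL/6. Over 100 draws that permuted residuals it was 1 against 717 for strain by depot. In each of these 10 comparisons only the real grouping reached the real count. A split that mixes the groups widens the spread within them, so low counts there were likely in any case. The splits cannot tell strain from library series. The 556 genes called for the drug in C57BL/6 in the fit of 16 libraries were not tested this way. For strain by rosiglitazone 2 of 100 draws, the real data included, reached the real count of 48, and the highest other draw called 61. That share lies under 0.05. Yet 1 draw made without an interaction called more genes than the real data, so chance is not excluded for this count.

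A library stood far from the others of its group in 42 of 393 gene and group pairs (10.7%), where chance gives about 1 in 20 for continuous values. In 16 of them the other libraries share 1 value, as rounding and quantile normalization can leave them, and the chance rate for such values was not worked out. In C57BL/6 iWAT replicate 4 the outlying values were Ucp1 2108 against 1 to 156, Cidea 2118 against 167 to 302, Otop1 413 against 59 to 115, Ppargc1a 227 against 77 to 102, Slpi 5 against 1 and Upk3b 5 against 1. Elsewhere in C57BL/6 iWAT they were Prdm16 295 against 183 to 199 in replicate 1, Cox5b 86 against 143 to 154 and Hoxa10 53 against 41 to 43 in replicate 2, and Hal 11 against 1 in replicate 3. In 129S1/SvImJ iWAT they were Ucp1 2392 against 42 to 86 and Acly 6408 against 1298 to 1994 in replicate 4, and Tcf21 2 against 1 in replicate 1. On chow, 129S1/SvImJ replicate 2 had Lcn5 58238 against 7 to 27, Nnt 725 against 444 to 483 and Iigp1 20 against 61 to 74, and replicate 3 Trim12a 6 against 1 to 2.

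In C57BL/6 eWAT after 12 weeks, replicate 3 had Tbx15 21 against 2 to 3 and Adipoq 19917 against 21259, replicate 2 Cyp51 458 against 241 to 290, replicate 4 Hoxc10 2 against 1, and replicate 5 Fabp4 40624 against 45057. In 129S1/SvImJ eWAT after 12 weeks, replicate 1 had Thrsp 1852 against 4116 to 4275 and Trim12a 1 against 2, replicate 2 Ndufs5 6 against 2, replicate 3 Cx3cr1 10 against 19 to 20, and replicate 4 Mtrnr2l 40 against 64 to 67 and Tbx15 5 against 2. On the control diet, C57BL/6 replicate 1 had Idh3a 738 against 694 to 699 and Plin5 170 against 75 to 86, replicate 2 Sptlc3 1 against 4, and replicate 4 Col4a2 4531 against 5728 to 5931 and Ucp1 3 against 4. 129S1/SvImJ replicate 1 had Elovl3 5 against 1 and Etfa 350 against 298 to 306, replicate 3 Pmvk 487 against 292 to 320 and Tlcd2 277 against 171 to 188, and replicate 4 Trim12a 2 against 1. With rosiglitazone, C57BL/6 replicate 1 had Gpd1 9191 against 12430 and Otop1 51 against 125 to 136, and 129S1/SvImJ replicate 4 Etfa 768 against 664 to 676 and Fabp4 58431 against 69086. Fabp4 and Adipoq, among the most abundant transcripts, have identical values in libraries where they hold the same rank, as quantile normalization leaves them.

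The test of the difference between groups was called for 20 named genes (limma, log2 interaction). For strain by rosiglitazone these were Ucp1, BC090627 (1.14), Sorl1 (-1.83), Tlcd2 (-1.78), Tuba1a (-1.70), Nsdhl (-1.67), Ptges (-1.88) and Gpd1 (-0.96). The calls of Ucp1, Nsdhl, Ptges and Gpd1 were lost without some single libraries, as given in the Results. For strain by depot they were Slpi (4.46), Serpina3b (4.01), Tekt1 (3.48), Pecam1 (1.37), Mtrnr2l (-5.93), Snord22 (-4.24), Snora26 (-3.05), Spp1 (-3.41), Mmp2 (-1.73), Mmp3 (-2.03), Etfa (-1.49) and Foxo1 (-1.16).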

How the results depend on the processing

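The filters, array weights, the fits without libraries set apart, and the shared counts and list tests with single libraries left out were chosen after the result was seen, and the other alternatives were planned. No called value of a named gene reversed its direction under any alternative run. For the 211 gene values in the text, 1973 of 2024 values with a library left out kept direction and call, 24 lost the call and 10 gained one. The remaining 17 were values not called that changed sign near 0. Under the other alternatives 1229 of 1288 kept both, 23 lost and 28 gained the call, and 8 not called changed sign. The text holds the steadier of 305 candidates, narrowed after these fits were seen. For all candidates 2642 of 2969 kept both with a library left out (298 lost the call, 12 gained one), and 1741 of 1857 under the other alternatives (80 lost, 28 gained). The depth is unknown, and for genes near the floor of 1 the rounding limits what can be seen.

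Counts of called genes moved more than 1.5 times under some alternatives, and except where an alternative is stricter by construction the cause was not tested. With a log2 fold change of at least 1 they were 318 on chow, 845 between the strains on control diet, 106 for the drug in C57BL/6, 276 for the drug in 129S1/SvImJ, 29 for strain by rosiglitazone, 687 between the strains on the drug, 1221 between the strains in eWAT after 12 weeks, 199 between the strains in iWAT, 1121 between the depots in C57BL/6 and 383 for strain by depot, and 38 drug-responsive genes were shared by the strains. At an adjusted p under 0.01, 23 strain differences and 113 drug changes were shared. Array weights gave 3690 on chow, 84 for strain by rosiglitazone and 584 between the strains in iWAT, a second quantile normalization 29 for strain by rosiglitazone and 256 between the strains in iWAT, and a group mean of at least 20 244 between the strains in iWAT. Fits of only the groups compared gave 73 for the drug in C57BL/6, 1407 between the strains on the drug and 211 between the depots in 129S1/SvImJ, and fits without the libraries set apart 2597 on chow and 247 between the depots in 129S1/SvImJ. Of all 242 list tests 53 were called by fry, and these need not be among the 97 called above. That test asks whether members move one way and compares no set with other genes. The number was also used as a replicate block, though the pairing check set beforehand gave no ground for it. Counts were then 252 on chow, 1277 between the strains in eWAT after 12 weeks and 30 between the strains in iWAT. They were 1447 between the depots in C57BL/6, 155 between the depots in 129S1/SvImJ and 25 for strain by depot. Of the 211 gene values in the text 178 kept direction and call (232 of 305 for all candidates).

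With single libraries left out, counts ran from 655 (without C57BL/6 chow replicate 1) to 2564 (without 129S1/SvImJ chow replicate 2) on chow, 275 (without C57BL/6 rosiglitazone replicate 4) to 741 (without C57BL/6 rosiglitazone replicate 2) for the drug in C57BL/6, 788 (without 129S1/SvImJ control replicate 4) to 1158 (without 129S1/SvImJ control replicate 3) for the drug in 129S1/SvImJ, and 14 (without C57BL/6 rosiglitazone replicate 3) to 113 (without C57BL/6 rosiglitazone replicate 1) for strain by rosiglitazone. They ran from 1614 (without 129S1/SvImJ rosiglitazone replicate 1) to 2664 (without 129S1/SvImJ rosiglitazone replicate 3) between the strains on the drug, 68 (without C57BL/6 iWAT replicate 1) to 194 (without 129S1/SvImJ iWAT replicate 2) between the strains in iWAT, 231 (without 129S1/SvImJ iWAT replicate 4) to 435 (without 129S1/SvImJ iWAT replicate 2) between the depots in 129S1/SvImJ, and 424 (without C57BL/6 eWAT replicate 5) to 1122 (without C57BL/6 iWAT replicate 4) for strain by depot. Shared strain differences ran from 21 (without C57BL/6 iWAT replicate 2) to 88 (without 129S1/SvImJ chow replicate 2). In the other 3 comparisons and for shared drug changes and lists, counts ran from 3132 (without C57BL/6 control replicate 2) to 4072 (without C57BL/6 control replicate 4), 3853 (without C57BL/6 eWAT replicate 1) to 5123 (without 129S1/SvImJ eWAT replicate 1), 2226 (without C57BL/6 eWAT replicate 3) to 3130 (without C57BL/6 iWAT replicate 3), 158 (without C57BL/6 rosiglitazone replicate 4) to 309 (without C57BL/6 rosiglitazone replicate 2) and 91 (without C57BL/6 iWAT replicate 4) to 102 (without C57BL/6 rosiglitazone replicate 2). The causes were not tested. Genes called whichever library was left out numbered 58 of 387 in the iWAT strain comparison, 13 of 48 for strain by rosiglitazone and 3353 of 4973 between the strains in eWAT after 12 weeks. The pseudocount of 0.1, all transcript rows and a value of at least 2 left every count within 1.5 times. TMM, DESeq2 size factors and DESeq2 tests, which need counts, were not run, nor were the comparisons with F1 mice.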

Other observations

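Fatty acid synthesis went opposite ways between the strains in different experiments, all on low fat diet, a pattern noticed after the lists had been tested. Its median was 0.50 in eWAT on the control diet of the drug experiment and -1.20 and -1.05 in eWAT and iWAT after 12 weeks of low fat diet (129S1/SvImJ against C57BL/6), and the list was called in all 3 (adjusted p = 0.00232, 8.27e-07 and 3.07e-08), but in none with an estimated correlation (adjusted p = 0.674, 0.258 and 0.226). On chow its median was -0.33, not called (adjusted p = 0.0551). The difference between the experiments was not tested.

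Ucp1 varied between inguinal libraries within each strain. It lay between 1 and 2108 in the 4 C57BL/6 iWAT libraries and between 42 and 2392 in the 4 129S1/SvImJ ones, with the highest value in replicate 4 of each. Lymphocyte genes lay above the group median in the same libraries, by 4.31 and 2.02 log2 units, and also in 129S1/SvImJ iWAT replicate 1, by 3.32, where Ucp1 was 86. The relation was not tested, since each strain has 4 iWAT libraries. Skeletal muscle genes lay 2.59 above the group median in 129S1/SvImJ iWAT replicate 1.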
